A study of Mus musculus with 8 samples.

How the data were processed

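Whole-kidney RNA of wild-type and Utx Pax2-Cre mice was sequenced, per the labels' protocols after purification of mRNA on poly-T beads, random priming and second-strand synthesis with no step stated to mark the strand. The 8 libraries fall into 4 groups of 2: wild type, knockout, wild type 3 days after I/R and knockout 3 days after I/R. A 21-day point named in the shared protocol is not analysed here.

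The values are FPKM per gene, 1 column per library, for 54965 genes, in 1 table that the authors deposited with gene coordinates and a gene length per gene. Per the submitters' processing notes, featureCounts 1.5.0-p3 and DESeq2 1.20.0 were used with genome build GRCm39. The aligner, any filter, the strand setting of the counting and the FPKM formula are not given in the sources used here. The coordinates were checked against an annotation of build GRCm38: 54409 genes matched by identifier and 53499 of these had identical coordinates, so positions are printed as the file gives them, and they are those of GRCm38. Because strand use is not stated, reads of a gene and of an overlapping antisense gene cannot be told apart, and genes of families with near-identical members are given as uncertain.

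FPKM multiplied by gene length was a whole multiple of 1 step in every library, for 100% of values within a tolerance of 0.05 reads, so whole reads per gene could be recovered. Reads in genes came to 17367872, 18307096, 16856820, 18229109, 16780542, 18497835, 17834333 and 17707776 in wild type 1 and 2, knockout 1 and 2, wild type I/R 1 and 2 and knockout I/R 1 and 2. At that depth 3 reads, taken as the floor of a count of 0 in a library, correspond to between 0.154 and 0.208 FPKM for a gene of 1 kb. Such floors cover counting error only, since reads copied by PCR are not independent molecules. The library size behind the deposited FPKM was 0.857 to 1.07 times the reads in genes and lay within 0.994 to 1.00 times a median-ratio size factor. A scale of that kind takes most genes as unchanged on average. A chi-square test on recovered reads found replicates to differ by more than sampling noise in every group (mean of 8.76, 17.4, 9.99 and 4.28 per gene in wild type, knockout, wild type I/R and knockout I/R), so no pair was merged as a repeat of 1 library. Differences in library preparation would also exceed that noise, so this does not show that the libraries come from separate animals.

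Genes with a mean of at least 1 FPKM over the 8 libraries (13304 genes) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with the data.table package (version 1.17.8). Folds on this scale understate the change of low genes. A model with a mean for each of the 4 groups (4 residual degrees of freedom) was fitted to all libraries with a mean-variance trend in the empirical Bayes step (2.90 prior degrees of freedom). It gave I/R against none in each genotype, knockout against wild type in each treatment and the interaction. A model with genotype and I/R as terms (5 residual degrees of freedom) gave the knockout effect over both treatments. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 across the tested genes of a comparison. "Rose", "fell", "higher" and "lower" are used of single genes for calls.

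A collection of 50 gene lists of kidney segments, other cell types, injury, metabolism, immunity, proliferation and other tissues, with 919 entries, was fixed together with the comparisons, tests and most alternative settings before the data were examined. Of the entries 914 were found by symbol, 4 by an older symbol and 1 was not found. The 48 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the 48 lists. A list's median is over its tested members, and the count adjusted over the list alone uses only its members. Genes named in the text are the 8 with the largest log2 difference in each direction among called protein-coding genes with an ordinary symbol and, outside the interaction, with no overlap between the groups' libraries. To these were added up to 4 called members with the largest differences in each list described (or up to 2 with the highest mean where none was called), and Kdm6a, Pax2, Havcr1, Lcn2, Col1a1 and Mki67 throughout. Any other gene, such as Gm11702, the marker genes Cd79a, Adipoq and Upk3a and the clock genes, was chosen after its values were seen. Some genes selected in these ways are not reported here, and those under the rule stay in the counts over named genes.

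The procedure was tested on simulated data for knockout against wild type after I/R over 13300 genes. It called 72 of 98 genes changed 2-fold and 90 of 97 changed 4-fold, all in the right direction, with 5 calls among unchanged genes. A list of 20 genes raised 1.5-fold was called and 0 of 100 random lists were, and 100% of simulated reads were recovered exactly. The simulated genes varied independently, with a spread shared by genes of similar level. The list result therefore does not cover real genes that vary together, and the share of changed genes called may differ in the real data.

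The alternative settings fixed beforehand were a pseudocount of 0.1, no filter on low values, a mean of at least 5 FPKM, rescaling by median ratio or to an equal sum over genes, the replicate number as a block, no trend, only the libraries compared, and leaving out each library in turn. Limma-voom on the recovered reads with the authors' library sizes, also with a mean of at least 10 reads, and the list tests without wild-type replicate 1 were added after the data had been seen. Chance values for comparisons that share libraries come from 100 simulated draws of unchanged groups. Principal components were taken on the tested genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.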

Results

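Gene expression was measured by RNA sequencing in 8 mouse kidney samples of 2 genotypes. The knockout, named Utx Pax2-Cre in the labels, is directed at Utx (gene symbol Kdm6a), the X-linked gene of a histone demethylase, by a Cre recombinase expressed under Pax2, a transcription factor gene of the kidney-forming lineages. Kidneys were taken 3 days after ischemia-reperfusion (I/R), a model of acute kidney injury in which renal blood flow is stopped and restored, or without it. Each of the 4 groups held 2 samples. The labels of the samples without I/R do not state whether they had a sham operation, and no label ties a sample to an animal, so the p-values measure only the spread between these samples, which may be technical. Reads assigned to genes numbered between 16780542 and 18497835 per library. The first principal component held 65.3% of the variance and set the I/R libraries apart from the others, and the genotypes apart after I/R but not without it. The 4 libraries without I/R lay between -31.2 and -26.6 on it, the wild-type I/R libraries at 40.3 and 41.1, and the knockout I/R libraries at 15.8 and 19.2.

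The targeted gene was examined first. Kdm6a (ENSMUSG00000037369) lies on chromosome X from 18162575 to 18279936 on the plus strand. Its level was 2.75 ± 0.262 FPKM in wild type, 1.95 ± 0.0580 in knockout, 2.99 ± 0.0175 in wild type after I/R and 1.71 ± 0.165 in knockout after I/R (mean ± SD, n = 2, as for all levels below). The difference between knockout and wild type was -0.35 ± 0.10 (log2 ± SE) without I/R, which did not pass the limma test (adjusted p = 0.431), and -0.56 ± 0.10 after I/R, which did (adjusted p = 0.0295). In both treatments each knockout library lay below each wild-type library. The value after I/R no longer passed without wild-type I/R replicate 1 or 2 (adjusted p = 0.110 and 0.131) or without knockout I/R replicate 1 or 2 (0.20 and 0.113). Whole-kidney RNA includes cells outside the Pax2 lineage, and the deleted part of the gene is not given in the sources used here, so reads outside it would still count. Pax2 was 7.95 ± 2.03 FPKM in wild type and 12 ± 1.81 in knockout without I/R, and 7.81 ± 0.374 and 11.5 ± 0.485 after it, and neither knockout difference passed (adjusted p = 0.446 and 0.119).

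The first comparison asked how the wild-type kidney had changed 3 days after I/R. All 27 tubular injury genes, all 20 cell cycle genes, 24 of 25 extracellular matrix genes and 14 of 15 macrophage genes rose, and 27 of 30 amino acid catabolism genes and 16 of 17 tricarboxylic acid cycle genes fell. With an estimated correlation the adjusted p was 0.152 for the tubular injury list and 0.153 for each of the others. Havcr1 (ENSMUSG00000040405, chromosome 11, from 46735080 to 46779578), which encodes the tubular injury marker KIM-1, rose from 0.911 ± 0.230 to 223 ± 26.3 FPKM, a log2 difference of 6.87 ± 0.11 (adjusted p = 1.44e-06). Lcn2, which encodes the iron-siderophore-binding injury marker NGAL, rose from 0.622 ± 0.0464 to 105 ± 27.3 FPKM. Slc22a7, an organic anion transporter gene of the proximal tubule, fell from 117 ± 22.1 to 5.77 ± 2.06 FPKM. In all, 4992 of 13304 tested genes passed, 2319 of them higher and 2673 lower, and 1102 of these differed by at least 2-fold.

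The largest increases after I/R in wild type included Timp1, an inhibitor of matrix metalloproteinases (4.71 on the log2 scale), the fibrillar collagen gene Col3a1 (4.60), the keratin gene Krt20 (4.52), the calcium-binding protein gene S100a6 (4.40) and Aldh1a2, a gene of retinoic acid synthesis (4.28). Sprr2f, of a family of small proline-rich proteins, was listed at 0 in both wild-type libraries without I/R and reached 21.5 ± 4.64 FPKM after it. Large decreases were seen for Inmt, a methyltransferase gene (-3.87), Dnase1 (-3.57) and Cyp7b1, an oxysterol hydroxylase gene (-3.37). Serpina1d, Cyp2d9, Cyp2d12 and the hemoglobin gene Hbb-bt fell by 3.63, 3.36, 3.13 and 3.17, but reads of these genes, and of Sprr2f, may be shared with near-identical family members, so their values are uncertain.

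All 27 tested genes of the tubular injury and repair list rose in wild type, with a median of 2.61, and 27 passed when adjusted over the list alone. The list differed from the other genes by camera with its preset correlation (adjusted p = 1.06e-19) and not with an estimated one (adjusted p = 0.152 with an estimated correlation). All 20 cell cycle and mitosis genes rose (20 adjusted over the list alone; median 2.20), among them Cdc20 (3.11), Ccnb2 (2.84), Ube2c (2.78) and the proliferation marker Mki67 (2.72). Of 25 extracellular matrix genes 24 rose (24 adjusted over the list alone; median 2.09), Col1a1 by 4.23 and Col1a2 by 3.09. Of 15 macrophage and monocyte genes 14 rose (14 adjusted over the list alone; median 1.90), with Plac8 at 2.62, Cd14 at 2.59, the lysozyme gene Lyz2 at 2.48 and Cd68 at 2.09. These 3 lists had an adjusted p of 0.153 with an estimated correlation. In the complement and coagulation list 18 of 20 rose (18 adjusted over the list alone), with an adjusted p of 0.143 with an estimated correlation. The largest were C3 (4.18) and the fibrinogen genes Fgg (3.78), Fga (2.97) and Fgb (2.70). C3 differed widely between replicates, at 11.2 and 1.86 FPKM without I/R and 197 and 57.1 after it, so its size and rank are uncertain. Type I interferon response genes rose in 18 of 22 cases (20 adjusted over the list alone; median 1.02), Ifit3 by 1.71 and Isg15 by 1.53, with an adjusted p of 0.276 with an estimated correlation.

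Of 30 amino acid catabolism genes 27 fell in wild type (27 adjusted over the list alone; median -0.93), including Hpd, of tyrosine breakdown (-2.84). Of 27 fatty acid oxidation genes 22 fell (23 adjusted over the list alone; median -0.60), with Acsm3 at -2.14 and the acyl-CoA dehydrogenase gene Acadm at -1.48. Of 17 tricarboxylic acid cycle genes 16 fell (16 adjusted over the list alone; median -0.62), and these 3 lists had an adjusted p of 0.153 with an estimated correlation. Oxidative phosphorylation genes fell in 27 of 29 cases (27 adjusted over the list alone; median -0.53), with an adjusted p of 0.289 with an estimated correlation. Distal convoluted and connecting tubule genes fell in 10 of 12 cases (10 adjusted over the list alone; median -1.22), including the calcium-binding protein genes Pvalb (-3.13) and Calb1 (-2.14) and Slc12a3, the thiazide-sensitive sodium chloride cotransporter gene (-1.47), with an adjusted p of 0.161 with an estimated correlation. In the thick ascending limb list 9 of 14 fell (11 adjusted over the list alone), including the growth factor gene Egf (-2.92) and Slc12a1, the loop-diuretic-sensitive cotransporter gene (-1.3), with an adjusted p of 0.294 with an estimated correlation. All 12 male-biased kidney genes fell (12 adjusted over the list alone; median -1.82), with an adjusted p of 0.20 with an estimated correlation, and all 6 erythrocyte genes fell (6 adjusted over the list alone; median -2.82), with an adjusted p of 0.153 with an estimated correlation. Camera with its preset correlation called 28 of 48 lists, and fry also called these 28. None held its call with an estimated correlation, where the smallest adjusted p was 0.143. That setting called 0 lists in every comparison, so a failure there does not set 1 list apart from another. The share of reads from mitochondrial genes was 8.19 and 8.36% in the wild-type libraries without I/R and 5.93 and 6.31% after it. The scale matters for the balance of directions: when each library was rescaled to an equal sum, the median shift over all genes was 0.29, and 80.3% of called genes were higher against 46.5% as deposited, while no called list changed the sign of its median. Without wild-type replicate 2, 3181 genes passed.

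**Figure D1:**
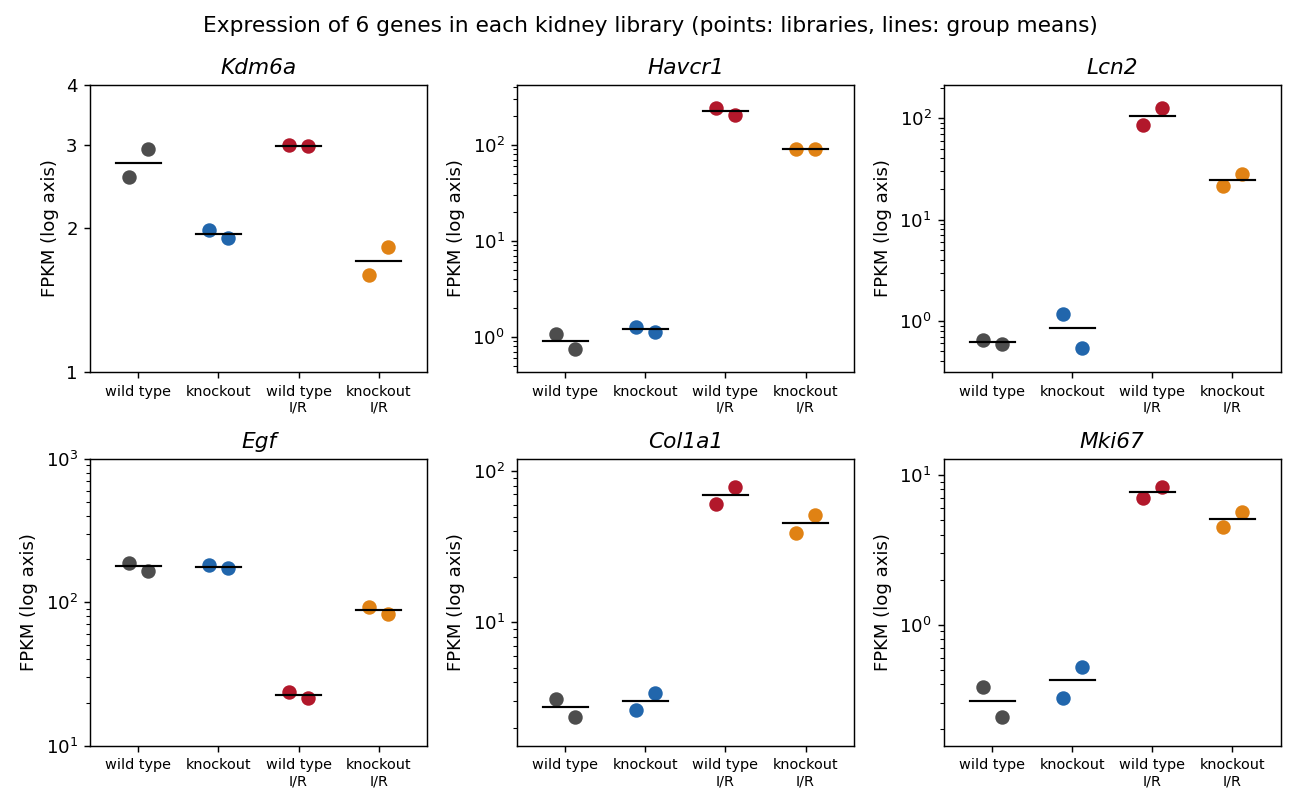
Level of 6 genes in each library, with FPKM on a log axis, a point per library and a line at the mean of each group of 2. Havcr1 lay between 0.749 and 1.26 FPKM in the 4 libraries without I/R, at 241 and 204 in wild type after I/R and at 90.2 and 89.6 in knockout after I/R.

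The second comparison asked the same of the knockout kidney. There 22 of 27 tubular injury genes, all 20 cell cycle genes, 24 of 25 matrix genes and 14 of 15 macrophage genes rose, and 24 of 30 amino acid catabolism genes fell (adjusted p = 0.170 with an estimated correlation for each of these lists). Havcr1 rose from 1.2 ± 0.0863 to 89.9 ± 0.397 FPKM (5.37 ± 0.11, adjusted p = 7.87e-06) and Lcn2 from 0.848 ± 0.442 to 24.7 ± 4.66 FPKM (3.80 ± 0.23, adjusted p = 4.40e-04). The complement gene C3 rose by 4.12, Col3a1 by 3.79, Col1a1 by 3.52, Aldh1a2 by 3.47, Timp1 by 3.31, Spp1, the osteopontin gene, by 2.97 and Mki67 by 2.10. Slc22a7 (-4.08), Cyp7b1 (-3.38), Serpina1d (-3.20) and Cyp2d9 (-2.50) were lower, as were the hemoglobin genes Hba-a1 (-2.69), Hbb-bt (-2.66), Hba-a2 (-2.44) and Hbb-bs (-2.43), whose reads may be shared within the family.

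In knockout, 2748 genes passed, 1191 higher and 1557 lower. Of the tubular injury genes 22 of 27 rose (23 adjusted over the list alone; median 1.46), and all 20 cell cycle genes rose (20 adjusted over the list alone; median 1.63). Of 25 matrix genes 24 rose (24 adjusted over the list alone; median 1.41) and of 15 macrophage genes 14 (14 adjusted over the list alone; median 1.63), including Lyz2 (2.33), Mrc1 (1.83) and Cx3cr1 (1.80). These 4 lists had an adjusted p of 0.170 with an estimated correlation. Antigen presentation genes rose in 5 of 8 cases (8 adjusted over the list alone), H2-DMa by 1.57, Cd74 by 1.29 and H2-Ab1 by 1.28, with an adjusted p of 0.170 with an estimated correlation. Interferon response genes rose in 17 of 22 (21 adjusted over the list alone), with an adjusted p of 0.175 with an estimated correlation. Amino acid catabolism genes fell in 24 of 30 (27 adjusted over the list alone; median -0.54), with an adjusted p of 0.170 with an estimated correlation, and oxidative phosphorylation genes in 20 of 29 (29 adjusted over the list alone; median -0.43), with an adjusted p of 0.256 with an estimated correlation. Distal convoluted and connecting tubule genes fell in 5 of 12 (6 adjusted over the list alone; median -0.30), with an adjusted p of 0.417 with an estimated correlation. All 12 male-biased genes fell (12 adjusted over the list alone) and 5 of 6 erythrocyte genes (6 adjusted over the list alone), with an adjusted p of 0.170 with an estimated correlation for both lists. The mitochondrial share was 8.51 and 8.10% without I/R and 7.56 and 7.38% after it. Rescaling to an equal sum gave a median shift over all genes of 0.25, and 85.2% of called genes were then higher against 43.3% as deposited. Again no sign changed among the 30 lists called by camera, of which fry also called 29. The count of genes was not stable when a library was left out. Such a fit leaves 1 sample in a group and fewer degrees of freedom, so the change cannot be assigned to the particular library. The count was 1790 with no filter on low values and 1556 when only these 4 libraries were fitted.

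Between the genotypes, 2331 genes passed for I/R in both and in the same direction, where independent lists would share 520, and 5 passed in opposite directions. No library enters both differences, but both tests use the same estimate of each gene's spread. Genes that vary little are more readily called in both, so 520 is not an exact chance level. Across genes, which are not independent replicates, the differences correlated with Pearson's r = 0.784 and Spearman's rho = 0.704, and the total-least-squares slope of knockout on wild type was 0.675. Of the 2331 genes, 81.1% had the smaller absolute difference in knockout.

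The third comparison asked what the knockout had changed without I/R. The only gene that passed was Gm11702 (ENSMUSG00000084277), a processed pseudogene of 69 bases on chromosome 11 from 115657491 to 115657559, named after its values were seen. It had 9 and 7 reads in the wild-type libraries and 0 in both knockout libraries, and such short copies can share reads with their parent gene, so its value is uncertain. Havcr1 was 0.911 ± 0.230 FPKM in wild type and 1.2 ± 0.0863 in knockout, Lcn2 0.622 ± 0.0464 and 0.848 ± 0.442, Col1a1 2.74 ± 0.542 and 3.01 ± 0.543, and Mki67 0.310 ± 0.0988 and 0.422 ± 0.140, and none of these passed (adjusted p = 0.595, 0.834, 0.880 and 0.810). At an unadjusted p under 0.05 there were 1233 genes, where 665 would be expected with no effect, and limma-voom on recovered reads called 0. Camera called 11 of 48 lists with its preset correlation. None of them held with fry, where the smallest adjusted p was 0.251, or with an estimated correlation, where it was 0.634. Of these, the unfolded protein response and heat shock list was lower in knockout (median -0.26, with Hspa8 at -0.60 and Herpud1 at -0.22, 0 of 18 passing and 8 lower adjusted over the list alone, adjusted p = 0.634 with an estimated correlation) and the oxidative phosphorylation list higher (median 0.16, 0 of 29 passing and 0 adjusted over the list alone, adjusted p = 0.695). The B and plasma cell list had a median of -1.40 with 0 of 7 passing, Igkc at -1.45 and Jchain at -1.28 (0 adjusted over the list alone, adjusted p = 0.657 with an estimated correlation). Wild-type replicate 1 stood apart in these genes: the B cell receptor gene Cd79a was at 6.94 FPKM there and 0.721 in replicate 2, and at 0.142 and 0.586 in knockout, and Igkc at 609.1 and 230.5 in wild type and 180.3 and 102.8 in knockout. Without that library the list median was -0.35 (camera adjusted p = 0.0922), and of the 11 lists 3 stayed called. The count was 6 without wild-type replicate 2. It was 2 without knockout replicate 1 or 2, without wild-type I/R replicate 1 or 2 or without knockout I/R replicate 1 or 2, and 10 with no filter on low values.

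The fourth comparison set knockout against wild type after I/R, the contrast closest to the study's question of how Utx loss alters the injured kidney. Of 27 tubular injury genes 18 were lower in knockout, and of 12 distal convoluted and connecting tubule genes 9 were higher (adjusted p = 0.182 with an estimated correlation for both lists). Lcn2 was 24.7 ± 4.66 FPKM in knockout and 105 ± 27.3 in wild type (-2.04 ± 0.23, adjusted p = 0.0119), and Havcr1 89.9 ± 0.397 and 223 ± 26.3 (-1.29 ± 0.11, adjusted p = 0.00824). Egf (ENSMUSG00000028017), highly expressed in the thick ascending limb and distal convoluted tubule, was 88.2 ± 6.68 FPKM in knockout and 22.6 ± 1.5 in wild type (1.92 ± 0.10, adjusted p = 0.00288). Of 800 genes that passed, 371 were higher and 429 lower in knockout, 110 of them by at least 2-fold.

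Among the genes higher in knockout after I/R were the calcium-binding protein genes Calb1 (1.99), Pvalb (1.92) and S100g (1.85), Slc12a3 (1.37), Dnase1 (1.39), the transporter gene Abca13 (1.39) and Cyp2d12 (1.99). Among those lower were the keratin genes Krt19 (-1.90) and Krt20 (-1.67), S100a6 (-1.86), the transcription factor gene Myc (-1.84), the mesothelin gene Msln (-1.69), Gprc5a (-1.68) and Sprr2f (-2.17). Col1a1 was 45.2 ± 9.08 FPKM in knockout and 69.5 ± 12 in wild type and Mki67 5.09 ± 0.850 and 7.66 ± 0.885, and neither passed (adjusted p = 0.107 and 0.0888). In the urothelium list 0 of 4 tested genes passed (2 lower adjusted over the list alone; median -1.35, adjusted p = 0.393 with an estimated correlation). Upk3a, of the urothelial plaque, was 4.22 and 2.40 FPKM in wild type after I/R and 0.415 and 0.257 in knockout after I/R, against 2.79 and 0.849 in wild type and 3.42 and 1.06 in knockout without I/R.

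Of the 27 tubular injury genes 18 were lower in knockout after I/R (24 adjusted over the list alone; median -1.04), and 9 of 18 DNA replication genes (16 adjusted over the list alone; median -0.50), with Rrm2, of nucleotide synthesis, at -0.85 and the replicative helicase gene Mcm5 at -0.81. These lists had an adjusted p of 0.182 with an estimated correlation. Immediate early genes were lower in 9 of 18 cases (15 adjusted over the list alone; median -0.88), including Egr2 (-1.33), Junb (-1.29) and Fos (-1.09), and cell cycle genes in 7 of 20 (20 adjusted over the list alone; median -0.51), with an adjusted p of 0.209 with an estimated correlation for both. Matrix genes were lower in 6 of 25 (20 adjusted over the list alone; median -0.52), with Timp1 at -1.04, with an adjusted p of 0.248 with an estimated correlation. Distal convoluted and connecting tubule genes were higher in 9 of 12 (11 adjusted over the list alone; median 0.96), intercalated cell genes in 6 of 12 (8 adjusted over the list alone; median 0.57), with Insrr at 1.21 and the pendrin gene Slc26a4 at 1.05, and amino acid catabolism genes in 14 of 30 (20 adjusted over the list alone; median 0.36), with Gatm, of creatine synthesis, at 0.98. For these 3 lists the adjusted p was 0.182 with an estimated correlation. Proximal tubule genes of segments S1 and S2 were higher in 7 of 19 (14 adjusted over the list alone), Slc22a8 by 1.05 and the glucose transporter gene Slc5a2 by 0.84, with an adjusted p of 0.290 with an estimated correlation. None of 22 interferon response genes passed (0 adjusted over the list alone; median -0.02, adjusted p = 0.983 with an estimated correlation), with Bst2 at -0.02 and Ifit3 at -0.42. Of 20 genes of the histone methylation machinery list the 1 that passed was Kdm6a (1 adjusted over the list alone). Camera called 31 of 48 lists, 24 of them also called by fry, and 0 held with an estimated correlation. Rescaling to an equal sum gave a median shift over all genes of -0.11 and left 21.8% of called genes higher against 46.4% as deposited, with no change of sign among the called lists.

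Most single calls between genotypes after I/R did not pass with 1 I/R library left out. The count was 8 without knockout I/R replicate 1, 10 without replicate 2 of that group, 78 without wild-type I/R replicate 1 and 46 without its replicate 2. It was 443 and 446 without wild-type replicates 1 and 2 and 1262 and 1257 without knockout replicates 1 and 2. Of the 101 calls for named genes, 5 passed without every library in turn: Pvalb, Egf, S100g, Myc and Krt20. Limma-voom on recovered reads called 1503 genes and the analysis with no filter on low values 305.

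These knockout differences were compared with the wild-type response, although both use the wild-type I/R libraries. Of the 429 genes lower in knockout after I/R, 410 had risen after I/R in wild type, and of the 371 higher genes 352 had fallen, where independent lists would share 74.8 and 74.5. Across genes r was -0.700 and the covariance -0.138. Simulated unchanged groups gave -0.501 and -0.0216, so part of the overlap may come from the shared libraries, which are too few to be split into sets of at least 2.

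The fifth comparison asked whether the I/R difference itself differed between genotypes. It did for 38 genes, 10 with a higher and 28 with a lower difference in knockout. This balance of directions depended on the setting, as given below. Of 27 tubular injury genes 11 had a lower I/R difference in knockout (adjusted p = 0.178 with an estimated correlation). Krt18 went from 8.64 ± 0.237 to 58.4 ± 9.41 FPKM in wild type and from 11 ± 1.26 to 19.0 ± 1.62 in knockout, an interaction of -1.87 ± 0.18 (adjusted p = 0.0302). The chaperone gene Clu went from 99.5 ± 11.9 to 777 ± 83.5 FPKM in wild type and from 129 ± 10.1 to 358 ± 14.4 in knockout (-1.48 ± 0.17, adjusted p = 0.0450). Egf went from 178 ± 16.1 to 22.6 ± 1.5 FPKM in wild type and from 177 ± 6.06 to 88.2 ± 6.68 in knockout (1.92 ± 0.14, adjusted p = 0.0261).

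Other genes with a lower difference in knockout were Krt20 (-1.68), the tight junction gene Cldn4 (-1.51), Havcr1 (-1.5), Phgdh, of serine synthesis (-1.49), and the chemokine gene Ccl20 (-1.49). Lcn2 did not pass (-2.20 ± 0.32, adjusted p = 0.0615), nor did Col1a1 (-0.72, adjusted p = 0.245), Mki67 (-0.63, adjusted p = 0.20) or Kdm6a (-0.21, adjusted p = 0.483). Genes with a higher difference in knockout were Pvalb (1.67), S100g (1.57), Abca13 (1.57), Slc26a4 (1.35), the proton pump gene Atp4a (1.3), Galnt11 (0.83) and Cd8a, the T cell coreceptor gene (1.98). Cd8a was 2.76 ± 0.334 FPKM in wild type without I/R (2.52 and 2.99 in replicates 1 and 2) and 0.438 ± 0.215 in knockout without I/R.

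Of 27 tubular injury genes 11 had a lower I/R difference in knockout (19 adjusted over the list alone; median -1.19, adjusted p = 0.178 with an estimated correlation). Of 18 immediate early genes Myc alone passed (9 adjusted over the list alone; median -0.88, adjusted p = 0.296 with an estimated correlation). Of 12 distal convoluted and connecting tubule genes Pvalb alone passed (9 adjusted over the list alone; median 0.97, adjusted p = 0.178 with an estimated correlation), and of 12 intercalated cell genes Slc26a4 alone (7 adjusted over the list alone; median 0.74, adjusted p = 0.178). Matrix genes had a median of -0.52 with 0 of 25 passing (3 adjusted over the list alone, adjusted p = 0.348 with an estimated correlation). The count of 38 was not stable when a library was left out. Such a fit leaves 1 sample in a group and fewer degrees of freedom. The change therefore cannot be assigned to the particular library left out. A pseudocount of 0.1 gave 14 genes, 7 of them with a higher difference in knockout. A mean FPKM of at least 5 gave 96, 40 of them higher, and limma-voom on recovered reads 175, 101 of them higher. The excess of lower differences among the 38 genes therefore did not hold under every setting. Of the 38 genes, 13, 30 and 28 passed under these settings in turn.

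**Figure D2:**
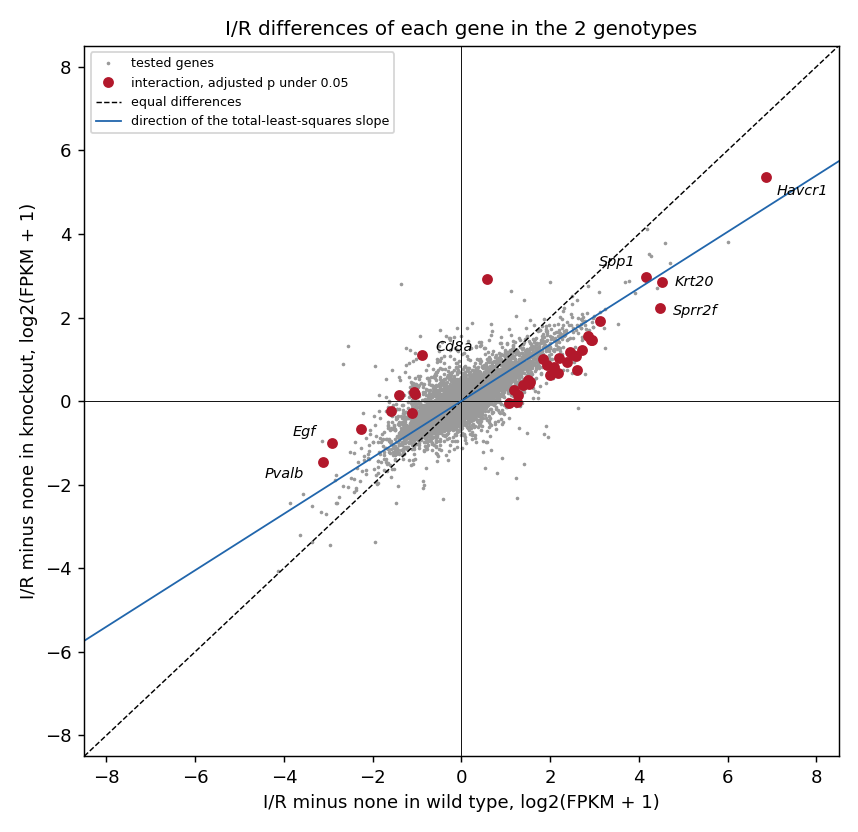
Log2(FPKM + 1) difference of each tested gene after I/R in wild type (horizontal axis) and in knockout (vertical axis), with the 38 interaction genes as large points, equal differences as a dashed line and the total-least-squares slope of 0.675 as a solid line. Havcr1 lies at 6.87 and 5.37, Egf at -2.92 and -1.0, and the unlabelled large point at 0.57 and 2.91 is Gm11702.

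**Figure D3:**
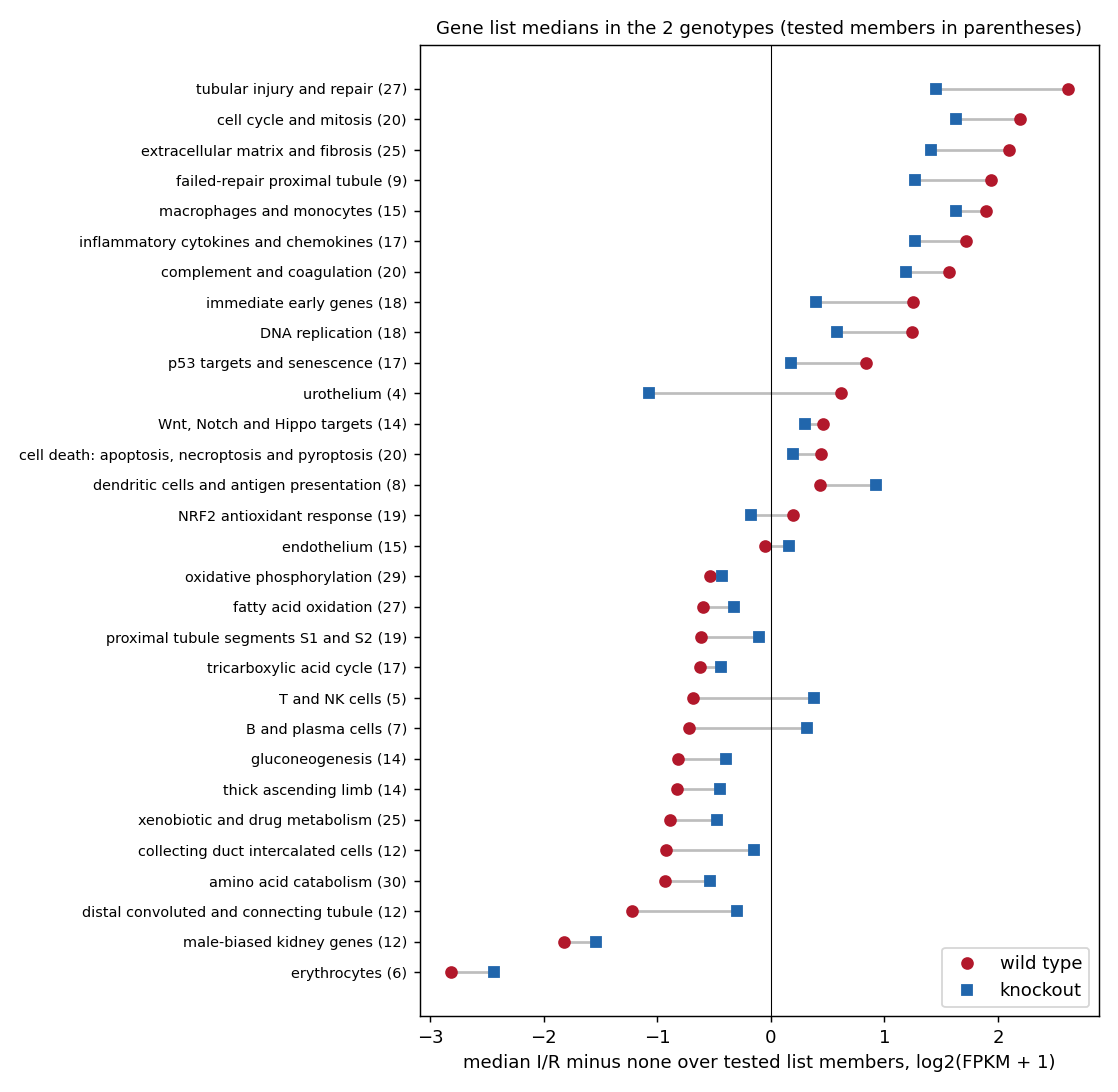
Median log2(FPKM + 1) difference after I/R over the tested members of the 30 lists that camera called for the interaction with its preset correlation, with a circle for wild type and a square for knockout. The tubular injury list has medians of 2.61 and 1.46 and the distal convoluted and connecting tubule list -1.22 and -0.30. Rescaling each library to an equal sum moves 4 of the 60 points across 0, namely endothelium in wild type and NRF2 response, proximal tubule S1 and S2 and intercalated cells in knockout.

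The knockout effects without and after I/R showed little relation across genes (r = 0.0643, rho = 0.0563). This r was -0.00918 without wild-type replicate 1, -0.0315 without knockout replicate 2 and 0.145 without knockout replicate 1. The last comparison averaged the knockout effect over both treatments, in a model with genotype and I/R as terms. No gene passed in limma, 1911 had an unadjusted p under 0.05, and limma-voom on recovered reads called 76. Leaving out knockout replicate 1 gave 2 genes and leaving out wild-type I/R replicate 2 gave 1. Kdm6a differed by -0.45 ± 0.08 (adjusted p = 0.156).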

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

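The tests of scaling between libraries, of the share of cortex and of the lists without wild-type replicate 1 were chosen only after the interaction had been seen. The test of a common factor was set out after the slope of the I/R differences between the genotypes was known and before its own result.

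The I/R difference differed between the genotypes, by limma's interaction term, for 38 genes. Of the named genes, the difference (knockout minus wild type, log2) was lower in knockout for Sprr2f at -2.24, Krt18 at -1.87, Krt20 at -1.68, Cldn4 at -1.51, Havcr1 at -1.5, Phgdh at -1.49, Ccl20 at -1.49, Clu at -1.48, Myc at -1.28 and Spp1 at -1.19. It was higher for Cd8a at 1.98, Egf at 1.92, Pvalb at 1.67, S100g at 1.57, Abca13 at 1.57, Slc26a4 at 1.35, Atp4a at 1.3 and Galnt11 at 0.83. Sprr2f, Krt20 and Ccl20 had 0 to 4 reads in each library without I/R, so their values depend on the pseudocount. With one of 0.1 they were -2.91, -1.805 and -1.75 and that of Cd8a was 3.403, and none of these 4 genes passed. At that setting Havcr1 (-1.68), Phgdh (-1.59), Clu (-1.49), Pvalb (1.98) and Galnt11 (0.83) did not pass either, although their differences were no smaller, nor did Myc (-1.15).

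Camera with its preset correlation gave an interaction for 30 of 48 lists, 16 of them also by fry and 0 with an estimated correlation (smallest adjusted p = 0.178). Of injury and growth lists, the median interaction was -1.19 for tubular injury, -0.58 for failed-repair proximal tubule, -0.88 for immediate early genes, -0.57 for cell cycle, -0.50 for DNA replication, -0.43 for p53 targets, -0.21 for cell death, -0.29 for the NRF2 response, -0.24 for Wnt, Notch and Hippo targets and -0.52 for extracellular matrix. Of immune and blood lists it was -0.28 for macrophages, -0.51 for cytokines and chemokines, -0.34 for complement and coagulation, 0.55 for T and NK cells, 1.23 for B and plasma cells, 0.59 for antigen presentation and 0.45 for erythrocytes. Wild-type replicate 1 stood apart in lymphoid and erythrocyte genes, and without it these last 4 medians were -0.023, 0.28, 0.40 and 0.045, with camera calling only the antigen presentation list among them (adjusted p = 0.0204). Of tubule and vessel lists it was 0.49 for proximal tubule S1 and S2, 0.31 for the thick ascending limb, 0.97 for the distal convoluted and connecting tubule, 0.74 for intercalated cells, 0.48 for male-biased genes, 0.24 for endothelium and -1.69 for urothelium. Of metabolic lists it was 0.28 for fatty acid oxidation, 0.12 for oxidative phosphorylation, 0.22 for the tricarboxylic acid cycle, 0.41 for gluconeogenesis, 0.36 for amino acid catabolism and 0.33 for xenobiotic metabolism.

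The I/R difference was smaller in size in knockout for 81.1% of the 2331 genes called in both genotypes in the same direction and for 64.5% of all 13304 tested genes. A scaling difference between libraries, which moves every gene alike, is argued against as the whole cause by the gap of 2.16 between the interaction medians of the distal convoluted and connecting tubule and the tubular injury lists. A milder response that shrinks every gene by 1 common factor stays open: after taking out the slope of 0.675, 8 of 28 lists called in wild type had a median remainder beyond the 0.2 set as the bound (such as 0.52 for the distal convoluted and connecting tubule, 0.44 for intercalated cells, -0.44 for immediate early genes and -0.30 for tubular injury), which goes against it, but camera called 20 lists with its preset correlation and 0 with an estimated one, fry called 0, and of single genes 1 (Gm11702, remainder 2.53, adjusted p = 0.0108) departed, with 1394 at an unadjusted p under 0.05. A different share of cortex in the samples also stays open. After I/R the distal list was higher in knockout by 0.96 and the podocyte list by 0.42, a gap of 0.54. Its 95% bootstrap interval across genes, 0.05 to 1.15, reaches below the 0.25 set as the bound. An effect of Utx loss on the response to I/R is the hypothesis the design names, and with 2 samples per group it cannot be told apart from a common factor set by how severe the injury was in single animals.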

How the results depend on the processing

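Limma-voom on recovered reads, with and without a mean of at least 10 reads, and the list tests without wild-type replicate 1 were chosen only after the results had been seen, and the other alternatives were set out beforehand. No called difference of a named gene and no called list changed direction under the alternatives run on it, except that without wild-type replicate 1 the T and NK cell medians for knockout without I/R and for the interaction crossed 0, to 0.011 and -0.023. The count of genes changed by I/R in wild type stayed within 1.5 times under each alternative except without wild-type replicate 2. A similar count need not hold the same genes. Under the alternatives other than leaving out a library, 66.9% (mean of at least 5 FPKM) to 99.3% (rescaling by median ratio) of the 4992 genes still passed. Rescaling to an equal sum kept 70.5% of them. Where a cause is not given, the cause was not tested.

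With no filter on low values, which adds genes to the adjustment, 1790 genes changed by I/R in knockout, 10 by knockout without I/R, 305 by knockout after I/R and 1 over both treatments. A mean FPKM of at least 5, which tests fewer genes, gave 96 interaction genes and a correlation of I/R effects between genotypes of 0.844. A pseudocount of 0.1 gave 2 genes for knockout without I/R, 14 for the interaction and a correlation of 0.721. Rescaling to an equal sum gave 2 genes for knockout without I/R. Fitting only the libraries compared, which leaves fewer samples, gave 1556 genes for I/R in knockout and 0 for knockout without I/R. Voom on recovered reads gave 0 genes for knockout without I/R, 1503 after I/R, 175 for the interaction and 76 over both treatments, and 0, 1605, 165 and 87 with a mean of at least 10 reads.

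The labels do not state whether the replicate numbers pair the samples. Across genes, the deviations of same-numbered samples from their group means had correlations between -0.0827 and 0.161. These values show no strong shared deviation. They cannot decide whether the samples are paired, since noise between so few libraries per group could hide a shared factor. With the number as a replicate block, 461 genes passed for knockout after I/R, 9 for the interaction and 1 over both treatments.

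Leaving out each library in turn, where the lone sample is assumed to vary like the other groups, gave 3181 to 5453 genes for I/R in wild type, 583 to 3305 for I/R in knockout, 1 to 6 for knockout without I/R, 8 to 1262 for knockout after I/R, 0 to 206 for the interaction and 0 to 2 over both treatments. The correlation of I/R effects lay between 0.704 and 0.777, and that of knockout effects between -0.0315 and 0.145, with -0.00918 without wild-type replicate 1 and -0.0315 without knockout replicate 2. Of 448 results for named genes, 173 no longer passed without knockout I/R replicate 1, 191 without its replicate 2, 121 and 124 without wild-type I/R replicates 1 and 2, 123 with no filter and 60 with the block. These 448 results include some that were not called at first. Of 240 list results 130 were called at first. All of these 130 no longer passed with an estimated correlation and 33 of them no longer passed with fry, while 11 other results passed with fry alone. Depth limits low genes most: 3 reads of a 1 kb gene are up to 0.208 FPKM.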

Other observations

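The clock genes were listed after 1 of them, Ciart, had been seen to fall. A condition of 2 standard errors on the median of Clock, Nfil3 and Cry1 was added after the value was seen. The tests on wild-type replicate 1 and their pseudocount were chosen only after its values were seen.

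All 9 failed-repair proximal tubule genes rose after I/R in wild type (9 adjusted over the list alone; median 1.94) and 8 of 9 in knockout (9 adjusted over the list alone; median 1.27), among them the adhesion molecule gene Vcam1 at 2.29 and 2.15 and the chemokine gene Ccl2 at 2.78 and 1.92. Their adjusted p was 0.153 and 0.170 with an estimated correlation. Of 17 p53 target and senescence genes 12 rose in wild type (12 adjusted over the list alone) and 6 in knockout (6 adjusted over the list alone), with Gdf15 at 2.91 and 1.46 and the cell cycle inhibitor gene Cdkn1a at 1.98 and 1.03. The adjusted p was 0.152 and 0.170 with an estimated correlation. Both lists share genes with the tubular injury list, so they are not separate evidence. Vcam1, Ccl2 and Havcr1 are also in the failed-repair list, and Gdf15 and Cdkn1a in the p53 list. Proximal tubule segment S3 genes fell in 11 of 14 cases in each genotype (12 adjusted over the list alone in each), with medians of -1.02 and -0.80, and the amino acid transporter gene Slc7a13 at -2.55 and -2.05. Their adjusted p was 0.230 and 0.170 with an estimated correlation. Gluconeogenesis genes fell in 12 of 14 cases in wild type (12 adjusted over the list alone) and 6 of 14 in knockout (8 adjusted over the list alone), with Slc37a4, the glucose-6-phosphate transporter gene, at -1.2 and -0.75, and an adjusted p of 0.153 and 0.170 with an estimated correlation.

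Of 9 tested circadian clock genes of the negative limb and its output, 9 fell after I/R in wild type and 8 in knockout, and 5 were higher in knockout than in wild type after I/R. Ciart went from 15.6 ± 1.04 to 1.35 ± 0.177 FPKM in wild type and from 13.5 ± 1.18 to 3.27 ± 0.903 in knockout, and Dbp from 43.8 ± 3.50 to 11.5 ± 0.514 and from 43.7 ± 6.10 to 17.6 ± 1.73. The 9 genes were set against 3 tested genes labelled as the positive limb. Of those, Clock belongs to it, while Nfil3 and Cry1 encode repressors. A candidate explanation is a different time of day at collection, which was taken to part the 2 sets by over 1 on the log2 scale in both genotypes. The gap between their medians was 1.26 in wild type and 0.81 in knockout. Because Nfil3 and Cry1 are in the set, the gap cannot decide this. Time of day also cannot be told apart from I/R, since the labels do not give it. A general loss of tubule transcripts was not decided either. It was taken to put the median of the 3 genes below 0 and within 0.3 of the proximal tubule S1 and S2 median. The latter was -0.61 in wild type and -0.11 in knockout. The median of the 3 genes was 0.079 and 0.23, which lies 0.39 and 0.23 above the highest value so allowed. This exceeds 2 standard errors (0.089) of Clock, but the median is the value of Clock alone and that condition was added afterwards. Nfil3 rose (1.08 and 0.81), Clock and Cry1 did not pass, and Cry1 was at -0.24 and -0.047. Whole-kidney RNA also does not show which cells these genes come from.

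Wild-type replicate 1 held transcripts of other tissues. Adipoq, of fat cells, was at 2.90 FPKM there and at most 0.282 in the other 7 libraries. On log2(FPKM + 0.1), 12 of 12 B and plasma cell genes and 12 of 12 adipose genes were higher than in replicate 2, with medians of 2.77 and 3.41. The adrenal and skeletal muscle lists had medians of 0, with 3 of 11 and 5 of 12 genes higher and 1 and 3 lower. Their other members were equal in both libraries, and medians of 0 from such ties cannot show that these tissues did not differ. Macrophage genes were higher in 19 of 23 cases and lower in 4 (median 0.53). Neutrophil genes were higher in 11 of 15 and lower in 1 (median 0.50). Lymphoid and fat tissue in the sample is a candidate explanation for the B and plasma cell and adipose genes and for the T and NK cell list (median 1.59, 16 of 18 higher). It leaves the urothelium list (median 1.59, 8 of 10 higher) unexplained. Upk3a of that list was also higher in replicate 1 than in replicate 2 of knockout without I/R, so for this gene the difference was not particular to wild-type replicate 1. More blood alone is argued against for this pair of libraries only, since the B and plasma cell median exceeded the erythrocyte median of 0.95 by 1.81. The 95% bootstrap interval of this gap, 0.58 to 3.04, resamples genes, which may vary together. It does not measure the spread between samples. With a pseudocount of 1 the B and plasma cell, adipose and erythrocyte medians were 1.44, 1.66 and 0.78. The gap was then 0.66, for which no interval was computed.

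For the knockout effect over both treatments, the 34 splits of the 8 libraries that could be fitted gave up to 6 genes where the real one gave 0. A count of 0 makes it certain that all 34 gave at least as many, so the splits decide nothing.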
